A study of Danio rerio with 19 samples.

How the data were processed

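Gene expression was measured by RNA sequencing in 19 libraries of zebrafish cells sorted by fluorescent reporters. Per the labels' protocols, RNA was extracted with the RNeasy Micro kit, cDNA was made with a SMARTer kit, and libraries were prepared with Kapa Hyper reagents and sequenced as paired ends on 2 Illumina instruments. Which library ran on which instrument is not given in the sources used here, so the instrument was not used as a batch. GRCz10, TopHat2 and Partek are named in the submitters' processing notes, with no versions.

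The deposited table holds TPM (transcripts per 1000000) for 31953 genes in 19 columns, computed by the authors. TPM is relative to gene length and to the total of each library and keeps no depth, so the depth per library is unknown and no counting interval is given. Each deposited TPM column summed to about 93168.2 rather than 1000000. All values were therefore multiplied by 1 constant, 10.7333, which brings each column to 1000000 and leaves ratios between genes and libraries unchanged, but changes what a pseudocount or a minimum of 1 means. The design fixed at the start had named the values as deposited with no rescaling, so results on the deposited scale are given beside the others. All columns were matched to samples by their names, with 0 unmatched. The table held 19 gene names that a spreadsheet had turned into numbers, of which 18 were recovered through their gene identifiers. Of the identifiers, 26121 (81.7%) were found in a reference table of gene names, which was used for names alone. A total of 2878 genes share their name with another gene. No coordinates are given, because no genome or annotation of the authors' build was used here.

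Samples were grouped by their labels. Nothing in the labels says whether replicates came from separate clutches, so p-values measure only the spread between these samples, which may be technical. The tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined.

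Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (linear models with mean-variance trend and robust empirical Bayes, 2-sided), and P values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. One fit held the all-arch, fli1a-only and sox10-only libraries and tested 14270 genes with a mean TPM of at least 1. A second held the all-arch, hand2, dlx5a and edn1 mutant libraries and tested 13206 genes. Groups of 1 library (dlx5a) were assumed to vary like the other groups. For comparisons with 1 library per group no test was made: changes of at least 1 on the log2 scale with a TPM of at least 10 in the higher library were counted, and list medians were set against 10000 random lists of the same size drawn within 20 bins of mean expression.

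A total of 28 gene lists with 425 members were fixed, of which 419 members were found: arch neural crest, ventral Edn1-dependent, dorsal, intermediate and joint, Notch pathway, endothelin pathway, BMP targets, FGF targets, Wnt targets, Hedgehog targets, Fox genes of the arches, Hox genes, frontonasal and maxillary, cartilage and bone, endothelium, blood and macrophage, otic, glia and neural crest progenitors, pigment, neuronal, epithelium, skeletal muscle, heart, cell cycle, heat shock, dissociation stress, p53 targets, and retinoic acid and patterning. Lists were tested with camera, which asks whether the genes of a list rank above or below all other genes, with a preset correlation between genes of 0.01. With a correlation estimated from these libraries, 0 lists passed in any comparison. That variant rests on 6 or 4 residual degrees of freedom and has little power here. Even the pigment list, with all members called lower than in sox10-only cells, did not pass. Missing the threshold in this way is therefore no evidence that a list did not move. Fry, which asks whether the genes of a list move 1 way on balance and does not compare them with other genes, was an alternative.

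Named genes are members of the lists that fit a comparison, and, of genes past the threshold with a mean of at least 10 TPM in the higher group and no overlap between the groups' libraries, the 10 with the largest change in each direction. Some genes that fit these rules are left out of the text. Where 0 genes passed, the 5 with the smallest p in each direction are named as not past the threshold. Without replicates, list members and the 10 largest changes in each direction with at least 10 TPM are named. The genes edn1, jag1b, notch1a, fli1a, sox10, hand2 and dlx5a are always examined.

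Replicate numbers in the titles may pair libraries collected at one time. The deviations of same-numbered libraries from their group means had correlations across genes from 0.321 to 0.744, all above 0.1. All-arch and fli1a-only libraries gave 0.73, 0.445 and 0.652 for numbers 1 to 3, and all-arch and sox10-only libraries 0.744, 0.502 and 0.557. The third principal component, with 13.0% of the variance, set the libraries numbered 1 apart. The numbers were therefore taken to pair the samples, on this check and not on a statement of the labels. A fit with the number as a block was made beside each test whose groups share numbers, leaving out libraries without one.

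Alternatives were other pseudocounts and minimum values, median-of-ratios rescaling, quantile normalization, limma without trend or robust estimation, all libraries in 1 fit, the replicate block, other controls, and leaving out each replicate in turn. The steps were tested on simulated data with 100 genes changed at each size. A log2 change of 2 was called for 61 of 100 genes (14270 genes, all-arch versus fli1a-only), 68 (all-arch versus sox10-only), 49 (13206 genes, hand2), 22 (dlx5a), 28 (hand2 versus dlx5a) and 42 (edn1 mutant), and a change of 4 for 94, 94, 92, 77, 76 and 92. Unchanged genes called numbered between 4 and 7. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.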

Results

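RNA sequencing was used to measure gene expression in cells sorted from zebrafish embryos. The cells came from the pharyngeal arches, the embryonic segments in which neural crest cells, a migratory population, build the jaw and gill skeleton. Cells were sorted by 2 transgenes, fli1a:GFP, active in arch neural crest and in vessels, and sox10:DsRed, active in neural crest and its derivatives. Of the 19 libraries, 3 held wild-type double-positive cells of all arch domains, called all-arch cells here. A further 3 libraries held cells with GFP alone (fli1a-only, mixed cells with vasculature per the labels) and 3 held cells with DsRed alone (sox10-only, mixed cells with ear per the labels). Ventral arch cells were sorted by hand2 and sox10 reporters in 2 libraries and by dlx5a and sox10 reporters in 1, going by titles that do not name fli1a. All arch domains together were also sorted from edn1 mutants (2 libraries), from a jag1b mutant and its wild-type control (1 library each), and from embryos with heat-shock-driven Gal4 alone, with Edn1 or with the Notch intracellular domain, NICD (1 library each). The labels give 36 hours after fertilization as the stage of all libraries but the sox10-only ones, for which they give 20, 28 and 36 hours, while the series design calls them replicates collected at one time with the arch cells.

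Between 10883 and 15212 of 31953 genes reached 1 TPM per library. The 10 most abundant genes took between 19.8% and 67.5% of the TPM. Globin genes took 31.9%, 62.7% and 23.1% in the fli1a-only libraries and at most 1.39% in any other. Sequencing depth is unknown, because TPM keeps no depth.

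The genes that the sorts and lesions target were read first. Reporter genes used for a sort check the labels and are no finding. The gene fli1a stood at 43.3 ± 1.56 TPM (SD, n = 3) in all-arch cells, 28.2 ± 15.4 in fli1a-only cells and 2.16 ± 0.158 in sox10-only cells. The gene sox10 stood at 26 ± 17.8, 3.45 ± 1.63 and 818 ± 100.3 TPM in the same order. In the hand2 libraries hand2 itself reached 34428 and 25346 TPM against 741 ± 109 in all-arch cells. In the dlx5a library dlx5a stood at 1530.3 TPM against 669.9 ± 193, a log2 difference of 1.23 that did not pass the test (limma, adjusted p = 0.236). The gene edn1 was near the floor in arch cells of both genotypes, at 0.136, 0.428 and 0.549 TPM in the wild type and 0 and 0.246 in the mutant, so it checks nothing about the edn1 label. The gene jag1b stood at 5.85 TPM in the jag1b mutant library and 31.6 in its wild type. Heat-shock Edn1 gave 20.9 TPM of edn1 against 1.37 with Gal4 alone, and heat-shock NICD gave 40.9 TPM of notch1a against 4.3.

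The first comparison asked which genes set arch neural crest cells apart from the fli1a-only population. Called genes that rose in all-arch cells included members of the ventral, dorsal and arch neural crest lists, and those that fell included members of the endothelium and blood lists, while 0 lists passed camera with an estimated correlation. The Dlx homeobox genes, which pattern the arches, were among the largest increases: dlx3b stood at 295 ± 142 TPM against 17.2 ± 5.61 (log2 3.97, SE 0.42), dlx4a at 117 ± 46.4 against 6.29 ± 1.48, dlx5a at 669.9 ± 193 against 47.4 ± 20.7 and dlx2a at 946 ± 173 against 69 ± 28.8 (n = 3 and 3 throughout). The homeobox genes barx1 (log2 3.89) and gsc (log2 3.45) and the BMP antagonist grem2b (log2 3.52) rose by similar amounts. Limma's adjusted p for these 7 genes lay between 8.06e-05 and 2.79e-04. The median of all genes lay at 0.68 on the log2 scale, so list medians are given relative to the median gene.

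Of the lists fixed for arch cells, the ventral Edn1-dependent list had 9 of 12 members higher (9 adjusted over the list alone, median 2.13 relative to the median gene), among them hand2 (log2 3.07) and dlx4b (log2 3.86), with camera adjusted p = 1.64e-06 and adjusted p = 0.273 with an estimated correlation. The dorsal list had 7 of 12 members higher (10 adjusted over the list alone, 12 with the replicate number as a block), among them fgf20b (log2 3.32), nr2f1b (3.00) and the Notch ligand jag1b (2.51), with camera adjusted p = 5.13e-05 and adjusted p = 0.273 with an estimated correlation. In the intermediate list 3 of 5 members rose, with grem2b and emx2 (log2 3.38) among them (3 adjusted over the list alone, camera adjusted p = 0.0123 and adjusted p = 0.298 with an estimated correlation). The arch neural crest list had 12 of 16 members higher (14 adjusted over the list alone), with hoxa2b (log2 2.77) and the endothelin receptor gene ednrab (3.03) as examples (camera adjusted p = 9.48e-08 and adjusted p = 0.317 with an estimated correlation). Its member twist1a, at log2 1.64, did not pass (limma, adjusted p = 0.0669) but passed with the replicate block (adjusted p = 0.00179). The block called 6353 of 14270 genes higher in this comparison, so passing with it is weak support for any gene or list that rose. The Fox genes of the arches had 6 of 8 members higher, such as foxf1 (log2 2.49), and all 8 adjusted over the list alone (camera adjusted p = 0.00367 and adjusted p = 0.471 with an estimated correlation). The frontonasal and maxillary list had 4 of 7 higher (7 adjusted over the list alone or with the block), with lhx6 at log2 3.23 (camera adjusted p = 0.00248 and adjusted p = 0.361 with an estimated correlation).

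Genes that fell came next. Of 26 endothelial genes 23 fell (26 adjusted over the list alone, median -4.42 relative to the median gene, camera adjusted p = 1.04e-58 and adjusted p = 0.122 with an estimated correlation). Examples were the lymphatic and venous marker lyve1b (log2 -5.76), vsg1 (-6.01), the transcription factor gene sox18 (-5.75), clec14a (-5.22) and etv2 (-4.87), a regulator of the blood and vessel lineages. The vessel receptor gene kdrl, at log2 -1.20, did not pass (limma, adjusted p = 0.0706) but passed with the block (adjusted p = 0.00871). Of 17 blood and macrophage genes 9 fell (9 adjusted over the list alone, camera adjusted p = 2.20e-20 and adjusted p = 0.122 with an estimated correlation). Globin genes led them: hbbe1.1 stood at 1752 ± 2374 TPM against 128367 ± 68852, hbae3 at log2 -7.26 and hbbe2 at log2 -7.35, with gata1a (-5.28), a regulator of red cell genes, alas2 (-6.12), an enzyme of heme synthesis, and slc4a1a (-6.42) beside them, and the carbonic anhydrase gene cahz (-6.66) outside the list. Globin genes are near-identical copies, so reads may be split between them and their single values are uncertain. The ligand gene edn1 also fell, at 0.371 ± 0.212 TPM in all-arch cells against 6.71 ± 4.76 in fli1a-only cells (log2 -2.24, limma, adjusted p = 0.0203).

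Camera also placed the neuronal list below other genes, with 2 of 12 members lower (7 lower and 2 higher adjusted over the list alone, and the same numbers over all genes with the block), neurod1 at log2 -3.52 and stmn1b at -1.97 (camera adjusted p = 3.11e-07 and adjusted p = 0.273 with an estimated correlation). The Notch, glia, epithelium, skeletal muscle and heart lists lay below other genes too, with adjusted p from 1.18e-06 to 0.0137 and adjusted p from 0.348 to 0.59 with an estimated correlation. In these lists between 0 and 2 members passed over all genes in either direction, and between 0 and 4 adjusted over the list alone. With the block 7 Notch genes rose and 7 fell, and 6 epithelial genes fell. One gene called was olig2, a gene of glial and motor neuron precursors, at log2 -3.31. The other 14 lists (endothelin, BMP, FGF, Wnt, Hedgehog, Hox, cartilage, otic, pigment, cell cycle, heat shock, dissociation stress, p53 and retinoic acid) did not pass, with adjusted p from 0.0517 to 0.887. With the block Hedgehog targets (adjusted p = 0.0443) and heat shock genes (adjusted p = 0.0452) passed, and neither did with an estimated correlation (adjusted p = 0.62 and 0.422). Among Hox genes, which mark position along the body axis, hoxd4a rose by log2 2.82.

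Limma with Benjamini-Hochberg adjustment called 594 genes higher and 412 lower of 14270 tested. The replicate block gave 6353 higher and 879 lower, with 1003 of the 1006 genes shared. The split between higher and lower depended on scaling: median-of-ratios rescaling gave 239 higher and 994 lower, quantile normalization 603 and 802, the values with globin genes left out 175 and 774, and the deposited scale 1537 and 175. Single libraries moved the higher count, to 114 without all-arch replicate 2, 93 without all-arch replicate 3, 274 without fli1a-only replicate 1 and 4320 without fli1a-only replicate 3. Of 39 named genes called, 31 passed with each library left out in turn; foxd1 (log2 2.37), foxl1 (236 TPM against 41.8), cahz, alas2, slc4a1a, edn1, neurod1 and stmn1b lost their call without all-arch replicate 3 (adjusted p from 0.0514 to 0.168). Calls were also lost without all-arch replicate 1 (edn1 and stmn1b), all-arch replicate 2 (foxd1, foxl1 and edn1), fli1a-only replicate 1 (foxd1, edn1 and stmn1b) and fli1a-only replicate 2 (foxd1, foxl1 and stmn1b), with adjusted p from 0.0511 to 0.163. Under both rescalings 37 of the 39 named genes kept their call, and on the deposited scale all 39 did.

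**Figure D1:**
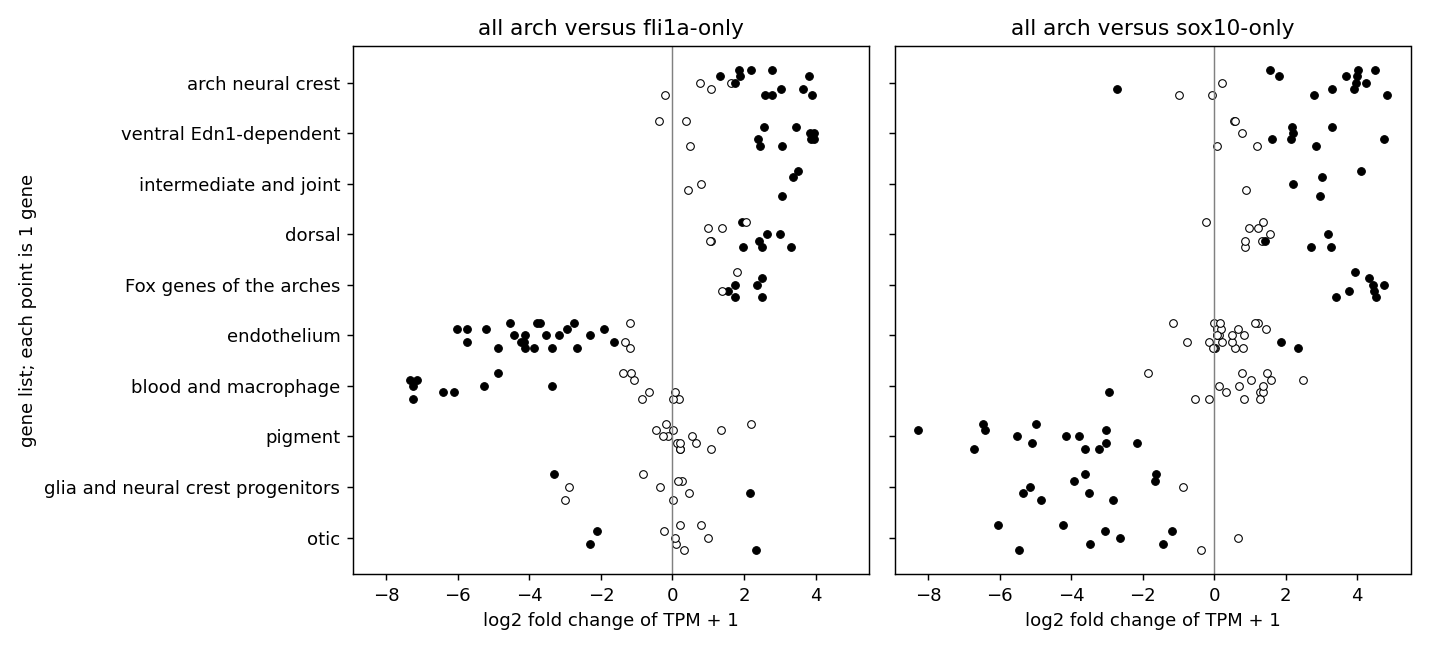
Log2 fold change of TPM + 1 of the members of 10 gene lists in all-arch cells against fli1a-only cells (left) and sox10-only cells (right). Each point is 1 gene, filled where limma's adjusted p passed 0.05, and the grey line marks 0. Endothelial genes lie left of 0 in the left panel, and all 14 pigment genes lie left of 0 in the right panel.

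The second comparison set all-arch cells against sox10-only cells. Called genes that rose included members of the Fox, arch neural crest and ventral lists, and those that fell included members of the pigment, neuronal, glia and ear lists, while 0 lists passed camera with an estimated correlation. All 8 Fox genes of the arches rose (8 adjusted over the list alone, median 4.43 relative to the median gene, camera adjusted p = 4.79e-14 and adjusted p = 0.123 with an estimated correlation), with foxd1 at 511 ± 204 TPM against 21.5 ± 14.5 (log2 4.75, SE 0.64) and foxl1 at log2 4.52. Of 16 arch neural crest genes 12 rose and 1 fell (the same numbers adjusted over the list alone, camera adjusted p = 1.66e-13 and adjusted p = 0.125 with an estimated correlation). Examples were barx1 at 699 ± 163 TPM against 23.8 ± 7.19 (log2 4.83), prrx1b (4.50), twist1a (4.23), pdgfra (3.98) and the endothelin receptor gene ednraa (3.92), while the related receptor gene ednrab fell by 2.72 to 16.6 ± 4.16 TPM from 117 ± 42.3 in sox10-only cells. The extracellular matrix gene fmoda (log2 4.61), the chemokine gene ccl25b (4.52), fgfbp2a (4.50) and ctgfb (4.66) were among the largest increases, with limma's adjusted p at most 3.54e-04 for the genes named so far that rose.

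Some members of the dorsal, intermediate and ventral lists rose as well. The intermediate list had 4 of 5 members higher (4 adjusted over the list alone, camera adjusted p = 1.19e-06 and adjusted p = 0.102 with an estimated correlation), the ventral list 7 of 12 (8 adjusted over the list alone, camera adjusted p = 7.78e-10 and adjusted p = 0.123 with an estimated correlation), with dlx4a at log2 4.75, and the dorsal list 4 of 12 (7 adjusted over the list alone, 9 with the replicate block, camera adjusted p = 2.07e-07 and adjusted p = 0.123 with an estimated correlation). Not every arch gene passed: dlx5a stood at 669.9 ± 193 TPM against 386 ± 52.6, jag1b at 36.1 ± 6.2 against 20.2 ± 8.25 and hand2 at 741 ± 109 against 319 ± 32.7, with adjusted p of 0.314, 0.26 and 0.138 by limma. Of these, hand2 passed with the block (adjusted p = 0.0192). The frontonasal list had 3 of 7 members higher (4 higher and 1 lower adjusted over the list alone, 5 and 1 with the block, camera adjusted p = 0.00103 and adjusted p = 0.359 with an estimated correlation). Of 26 endothelial genes 2 rose, kdrl among them at log2 2.34 (2 adjusted over the list alone, 5 over all genes with the block, camera adjusted p = 0.00951 and adjusted p = 0.681 with an estimated correlation).

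All 14 pigment genes fell (14 adjusted over the list alone, median -4.51, camera adjusted p = 1.36e-19 and adjusted p = 0.102 with an estimated correlation). They included gch2, an enzyme gene of pteridine pigment synthesis (245 ± 406 TPM against 16534 ± 10828, log2 -8.28), pnp4a (-6.47), a gene of iridophores, and the melanin genes tyrp1b (-6.42) and dct (-5.50), with their regulator mitfa at -3.04. The pigment list summed to 843 TPM in all-arch replicate 2 against 18.6 and 16.3 in the other two. Of 12 neuronal genes 11 fell (11 adjusted over the list alone, camera adjusted p = 4.16e-13 and adjusted p = 0.123 with an estimated correlation), such as neurod1 (log2 -5.06), stmn1b (-4.53) and isl1 (-4.23). Of 10 glia and progenitor genes 9 fell (10 adjusted over the list alone, camera adjusted p = 7.78e-10 and adjusted p = 0.125 with an estimated correlation), such as foxd3 (-5.33), a gene of early neural crest, sox2 (-5.15) and fabp7a (-4.83). With the block fabp7a missed the threshold (limma, adjusted p = 0.0559). Of 10 ear genes 8 fell (8 adjusted over the list alone, camera adjusted p = 2.96e-06 and adjusted p = 0.316 with an estimated correlation), with the otolith genes stm (-6.05) and otomp (-5.46) and the ear homeobox gene hmx2 (-4.22), while oc90, also an otolith gene, stood at 16.6 ± 2.7 TPM against 26.1 ± 18.2 and did not pass. Of 6 heart genes 3 fell (4 adjusted over the list alone, camera adjusted p = 0.00206 and adjusted p = 0.214 with an estimated correlation), with cmlc1 at log2 -5.87 and myl7 at -3.61. The epithelial genes cldnb (-6.15) and epcam (-5.16) fell, though their list of 21 did not pass camera (adjusted p = 0.139). Of 17 Hox genes 3 rose and 8 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.0489 and adjusted p = 0.681 with an estimated correlation), with the posterior genes hoxb7a (-5.48) and hoxb8a (-4.97) among those that fell. The genes rbp4l (-7.62), akr1b1 (-7.27) and guca2b (-7.03) were among the 10 largest decreases.

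The BMP, cell cycle and retinoic acid lists also passed camera, with adjusted p of 0.0262, 0.00357 and 0.0195, and adjusted p of 0.681 for each with an estimated correlation. With the block the Hedgehog (adjusted p = 0.0185) and blood lists (adjusted p = 0.0296) were added, and neither passed with an estimated correlation (adjusted p = 0.552 and 0.63). The other 10 lists did not pass in either fit, with adjusted p from 0.107 to 0.653 without the block. Limma called 485 genes higher and 1430 lower of 14270 tested, and the block 855 and 2080, with 1900 of 1915 genes shared. Median-of-ratios rescaling gave 959 higher and 1745 lower, quantile normalization 1324 and 1494, and the deposited scale 223 and 413. The sox10-only library of the arch stage taken alone gave 207 and 1021. Of 46 named genes called, 44 passed with each library left out in turn; gch2 lost its call without sox10-only replicate 2 (adjusted p = 0.0535), and sox2 without any library but all-arch replicate 2 (adjusted p from 0.0545 to 0.154).

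Genes higher than in both single-positive populations were taken as arch-enriched. There were 187 of them, and 184 lay at least 2-fold higher in both comparisons; 91 genes were lower than in both. Leading genes were dlx4a, barx1, dlx2a, grem2b, gsc and dlx1a (log2 3.64 and 3.30 against fli1a-only and sox10-only cells). The LIM homeobox gene lhx6 stood at 50.5 ± 13.1 TPM against 4.72 ± 2.39 and 1.9 ± 1.15, emx2 at 274 ± 78.6 against 26 ± 9.34 and 33.1 ± 8.69, and nr2f1b at 161 ± 42.1 against 19.4 ± 5.79 and 17.2 ± 6.29. The block gave 583 arch-enriched genes, quantile normalization 346 and the values with globin genes left out 112. The count fell to 70 without all-arch replicate 2, 58 without all-arch replicate 3 and 115 without fli1a-only replicate 1, and was 324 without fli1a-only replicate 3 and 91 with the sox10-only library of the arch stage alone.

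The third comparison asked how ventral hand2 cells differ from all arch cells. Some dorsal, frontonasal and cartilage genes were called lower in the hand2 libraries, and some heart and Hox genes and 1 neuronal gene higher, while 0 lists passed camera with an estimated correlation. The tight junction gene cldn11a stood at 1.09 ± 0.602 TPM (SD, n = 2) against 239 ± 67.2 (n = 3), a log2 change of -6.84 (SE 0.36, limma, adjusted p = 0.0022). The homeobox gene emx2 (log2 -5.33), the chemokine gene ccl25b (-5.29), the matrix gene tnw (-5.25) and the peptide genes adma (-5.07) and npb (-4.96) were also lower. The median gene lay at -0.12.

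Of 12 dorsal genes 4 fell (7 adjusted over the list alone, median -1.30 relative to the median gene, camera adjusted p = 1.01e-06 and adjusted p = 0.0992 with an estimated correlation): pou3f3a from 204 ± 112 to 5.49 ± 3.89 TPM, pou3f3b (log2 -2.92), fgf20b (-3.64) and jag1b (-2.31). Of 5 intermediate genes 2 fell, emx2 and grem2b (log2 -1.88), and 4 adjusted over the list alone (camera adjusted p = 3.60e-06 and adjusted p = 0.0992 with an estimated correlation). The joint gene irx7, at log2 -2.80, passed only with the block (limma, adjusted p = 0.0957, and 0.0402 with it). Of 7 frontonasal genes 3 fell, among them alx1 (-4.06) and alx4a (-1.68), and 4 adjusted over the list alone (camera adjusted p = 1.77e-04 and adjusted p = 0.347 with an estimated correlation). In the cartilage list matn4 (-3.57) and col9a1a (-3.87) fell, 2 of 14 (6 adjusted over the list alone, 4 over all genes with the block, camera adjusted p = 1.42e-04 and adjusted p = 0.511 with an estimated correlation), and the cartilage collagen gene col2a1a stood at 2.49 ± 1.77 TPM against 66.7 ± 42.9 without passing. The endothelin receptor genes ednraa (-2.71) and ednrab (-3.06) and the crest regulator tfap2a (-2.16) fell. Among ventral genes hand2, used for the sort, was the 1 of 12 that rose, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 5.67e-04 and adjusted p = 0.352 with an estimated correlation). For example dlx5a stood at 1330.0 ± 375 against 669.9 ± 193 TPM and dlx4b at 130.3 ± 8.99 against 69.7 ± 12.6, neither past the threshold. The gene barx1, at 1660.0 ± 426 against 699 ± 163 TPM, passed only with the block (limma, adjusted p = 0.228, and 0.0341 with it).

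Of 8 heart genes 3 rose (7 adjusted over the list alone, median 3.00 relative to the median gene, camera adjusted p = 1.09e-12 and adjusted p = 0.162 with an estimated correlation). They were the muscle protein genes cmlc1 (130.1 ± 94.7 TPM against 0.537 ± 0.93, log2 6.35), myl7 (4.18) and vmhc (2.26), and the heart hormone gene nppb, outside the list, stood at log2 4.47. With the block myh6, at log2 4.42, passed too (limma, adjusted p = 0.0575, and 0.0443 with it). Hox genes were higher as a list (2 of 17, hoxb5b at log2 2.15 and hoxb1b at 1.81, and 10 adjusted over the list alone; 7 and 15 with the block, hoxa2b among them at log2 1.27), with camera adjusted p = 4.92e-15 and adjusted p = 0.162 with an estimated correlation. Outside the list, the posterior Hox genes hoxd9a (4.56), hoxd11a (4.15) and hoxa13b (4.09) rose, and within it hoxb8a stood at 49 ± 37.3 TPM against 7.74 ± 3.13 without passing. Whether the posterior Hox RNA came from arch cells or from other cells with hand2 in the gate was not tested. In the neuronal list phox2bb, a gene of autonomic neurons, was the 1 of 9 that rose, at 440.1 ± 151 TPM against 27.2 ± 16.5 (2 adjusted over the list alone, 2 and 3 with the block, camera adjusted p = 1.42e-04 and adjusted p = 0.373 with an estimated correlation). In the epithelial list krt5 (log2 3.43) was the 1 of 18 (2 adjusted over the list alone, 5 and 12 with the block, camera adjusted p = 1.81e-06 and adjusted p = 0.373 with an estimated correlation). The Notch ligand genes dll4 (1.95) and dla (1.72) rose while their list did not pass (adjusted p = 0.15). The hairy-related gene her7 (4.08) rose and lost its call with the block (limma, adjusted p = 0.0572), and the vessel gene kdrl fell by 2.20. Cell cycle genes lay above other genes with 0 members called (camera adjusted p = 6.53e-04 and adjusted p = 0.56 with an estimated correlation), and skeletal muscle genes passed only with the block (adjusted p = 0.178, and 0.00773 with it, or 0.608 with it and an estimated correlation). The other 17 lists had adjusted p from 0.0532 to 0.907.

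Limma called 39 genes higher and 166 lower of 13206 tested. The block gave 94 and 290 of 13292, with 195 of 205 genes shared, and the deposited scale 18 and 66. The counts fell with any library left out. They were 8 higher and 46 lower without all-arch replicate 1, 11 and 53 without all-arch replicate 2, and 10 and 39 without all-arch replicate 3. Leaving out either of the 2 hand2 libraries left 1 in that group, assumed to vary like the other groups. A smaller fit has less power, so lost power and the weight of single libraries cannot be told apart. Of 34 named genes called, 10 passed with each of these 5 libraries left out in turn: hand2, cmlc1, hoxd11a, cldn11a, emx2, ccl25b, tnw, adma, npb and fgf20b. The other 24 lost their call without at least 1 of them (adjusted p from 0.0524 to 0.316). Leaving out the replicate 1 libraries of all groups together left 1 library each of the hand2, dlx5a and edn1 mutant groups. The spread then came from all-arch libraries alone, so that fit could not test these calls. Of the 34 named genes called, 30 kept their call under both rescalings and 27 on the deposited scale.

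**Figure D2:**
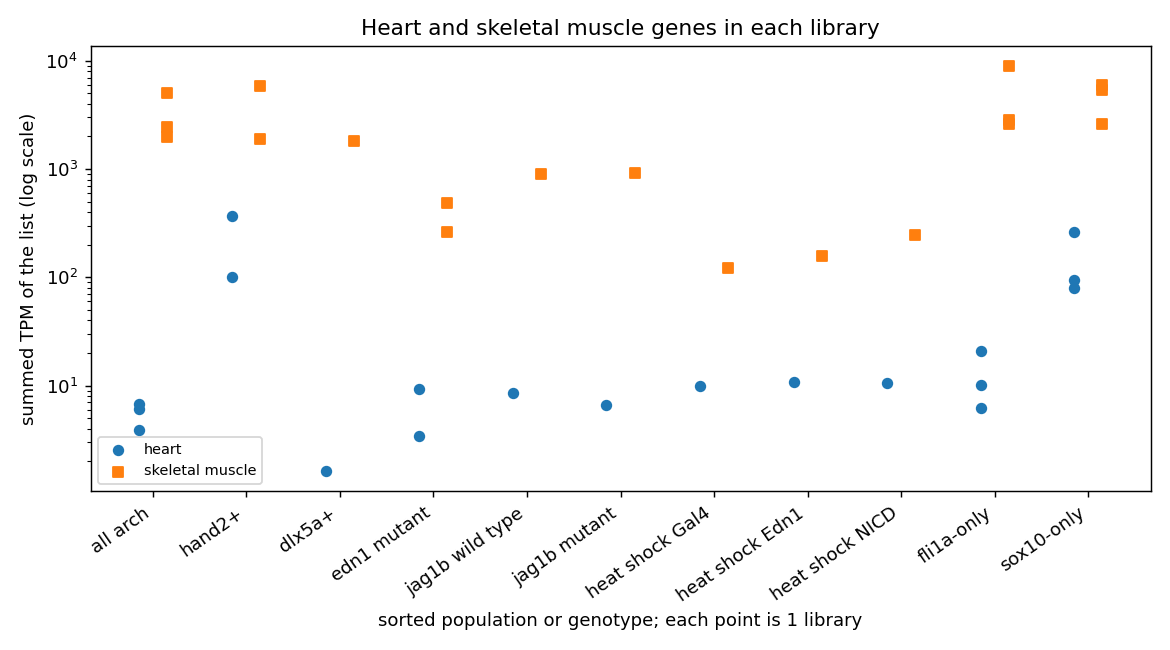
Summed TPM of the heart list (circles) and the skeletal muscle list (squares) in each library, on a log axis. Each point is 1 library. Heart genes reach 101 and 369 TPM in the hand2 libraries against at most 6.73 in all-arch cells and 93.7, 261 and 79.9 in sox10-only cells, and muscle genes lie at 489 and 260.3 TPM in the edn1 mutant against at least 1979.5 in all-arch cells.

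The dlx5a library was set against all-arch cells in the same fit. It is a single library, assumed to vary like the other groups, so its p-values rest on the spread of other groups and on the all-arch libraries. The calls held 1 gene each of the epithelium and ear lists that was higher and 3 of the frontonasal list that were lower, and 0 lists passed camera with an estimated correlation. The claudin genes CLDN22 (244 TPM against 3.08 ± 1.83, log2 6.03, SE 0.58), cldnb (5.47) and cldnj (4.01), which encode tight junction proteins, the ear homeobox gene hmx2 (4.24) and zwi (3.32) were higher. The genes cldn11a (-6.44), adma (-6.32), ca6 (-4.70), vcam1 (-4.50), aspn (-4.47) and npb (-4.30) were lower. Under that assumption limma's adjusted p lay between 0.0164 and 0.0394 for these genes of both directions, and none of them kept its call with each all-arch replicate left out in turn. The median gene lay at -0.38.

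Of 7 frontonasal genes 3 fell, among them alx1 (log2 -4.26) and alx4a (-2.80; 3 adjusted over the list alone, camera adjusted p = 0.0209 and adjusted p = 0.706 with an estimated correlation). Of 5 ear genes hmx2 passed, and stm (log2 4.97) and otomp (4.06) were added adjusted over the list alone, with 1 lower (camera adjusted p = 1.59e-04 and adjusted p = 0.354 with an estimated correlation). Of 18 epithelial genes cldnb passed, and epcam (4.46) was added adjusted over the list alone (camera adjusted p = 1.23e-06 and adjusted p = 0.688 with an estimated correlation). The genes hmx2, stm, otomp, cldnb and epcam were also higher in sox10-only than in all-arch cells. The ear list summed to 172 TPM in the dlx5a library, from 71.7 to 109 in all-arch cells and from 127 to 534 in sox10-only cells. Ear or other cells without fli1a in the dlx5a gate, whose title does not name fli1a, stay open as a source and were not tested. No ventral gene passed over all genes, and 4 of 12 were higher adjusted over the list alone (camera adjusted p = 1.23e-06 and adjusted p = 0.354 with an estimated correlation). Their levels were 458 TPM of dlx4a against 117 ± 46.4, 260.1 of dlx4b against 69.7 ± 12.6, 27.5 of dlx6a against 6.59 ± 2.6 and 2448 of hand2 against 741 ± 109, while dlx3b, at 928 against 295 ± 142, did not pass in that way either. In the intermediate list 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0193 and adjusted p = 0.354 with an estimated correlation), with irx7 at 218 TPM against 47.7 ± 25.9 and nkx3.2 at 388 against 134 ± 30.2, and neither passed over all genes. The dorsal ligand gene jag1b stood at 7.34 TPM against 36.1 ± 6.2 and hoxb5a at 4.05 against 38.1 ± 21.1, without passing. The endothelium list (kdrl at log2 -2.85, 1 of 13, 3 adjusted over the list alone, camera adjusted p = 0.0239 and adjusted p = 0.764 with an estimated correlation) and the blood list (0 of 14, also adjusted over the list alone, camera adjusted p = 0.0209 and adjusted p = 0.769 with an estimated correlation) lay below other genes. The other 21 lists had adjusted p from 0.106 to 0.84. Limma called 10 genes higher and 42 lower of 13206, with both rescalings near an even split (36 and 36 with median of ratios, 23 and 23 with quantiles) and 4 and 4 on the deposited scale. The counts were 0 and 0 without all-arch replicate 1 or 3, and 2 and 6 without all-arch replicate 2, and 0 of the 14 named genes called passed in each (adjusted p from 0.0523 to 0.124 where lost).

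Between the hand2 and dlx5a populations limma called 0 genes, with 1407 genes at an unadjusted p under 0.05. The median-of-ratios rescaling gave 3 higher and 9 lower, the quantile one 3 and 11 and the deposited scale 3 and 6. The genes with the smallest p, none past the threshold, included the transcription factor gene mecom (log2 3.24), dll4 (3.47), the receptor gene ret (22.9 TPM against 0.364) and hoxb1b (3.68) on the hand2 side and emx2 (-5.91), CLDN22 (-6.20), slc16a12b (-3.02) and zwi (-3.18) on the dlx5a side, with adjusted p from 0.0574 to 0.0966. The reporter genes stood at log2 3.59 (hand2) and -0.23 (dlx5a). Of the lists, 4 of 5 intermediate genes were lower in the hand2 cells adjusted over the list alone (camera adjusted p = 5.56e-09 and adjusted p = 0.0812 with an estimated correlation), such as irx7 (log2 -5.12) and grem2b (-2.58). Hox genes (10 of 17 higher adjusted over the list alone, camera adjusted p = 1.43e-07 and adjusted p = 0.318 with an estimated correlation) and heart genes (7 of 8 in the same way, cmlc1 at log2 5.81, camera adjusted p = 1.13e-08 and adjusted p = 0.237 with an estimated correlation) were higher, and 3 of 5 ear genes were lower with 1 higher, also adjusted over the list alone (camera adjusted p = 8.36e-05 and adjusted p = 0.172 with an estimated correlation). None of these passed over all genes, and the dlx5a side is 1 library. The other lists past camera were endothelium, blood and heat shock above other genes and dorsal, cartilage, Wnt and ventral below them, with adjusted p from 1.30e-06 to 0.0383 and adjusted p from 0.172 to 0.663 with an estimated correlation. The other 17 lists had adjusted p from 0.0769 to 0.969.

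The edn1 mutant comparison asked which genes differ in mutants of edn1, whose product is a secreted signal for ventral arch identity. The labels name no genotyped control of these mutants. The wild-type all-arch libraries stood in as controls, so differences may also reflect how the libraries were collected. Ventral Dlx genes were lower in both mutant libraries than in all 3 all-arch libraries. Only dlx4b passed over all genes, at 2.92 ± 0.0169 TPM (SD, n = 2) against 69.7 ± 12.6 (n = 3), a log2 change of -4.16 (SE 0.23, limma, adjusted p = 0.00606). The related genes stood at 15.3 ± 11.5 against 295 ± 142 TPM for dlx3b (log2 -4.28), 6.31 ± 1.54 against 117 ± 46.4 for dlx4a (-3.96), 229 ± 28.3 against 669.9 ± 193 for dlx5a (-1.52) and 0.765 ± 0.527 against 6.59 ± 2.6 for dlx6a (-2.09), and none of these 4 passed, with limma's adjusted p at 0.0852 for dlx4a and 0.338 for dlx3b. With msxe (-0.96), 6 of 12 ventral genes were lower adjusted over the list alone (median -0.69 relative to the median gene, camera adjusted p = 2.60e-14 and adjusted p = 0.161 with an estimated correlation). The ventral genes hand2, at 571 ± 156 against 741 ± 109 TPM, and gsc, at 213 ± 144 against 191 ± 54.5, were not among them. In the intermediate list nkx3.2 (log2 -2.28) and irx7 (-2.08), both joint genes, were lower adjusted over the list alone, 2 of 5 and 0 over all genes (camera adjusted p = 6.84e-04 and adjusted p = 0.161 with an estimated correlation), and grem2b stood at -0.61. The dorsal list lay above other genes with 0 members called either way (camera adjusted p = 0.00561 and adjusted p = 0.25 with an estimated correlation). For example pou3f3b stood at 1086 ± 136 against 586 ± 221 TPM and jag1b at 50.1 ± 17.9 against 36.1 ± 6.2.

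Skeletal muscle genes moved with this comparison: 16 of 20 were lower adjusted over the list alone and 0 over all genes (median -2.70, camera adjusted p = 2.45e-35 and adjusted p = 0.161 with an estimated correlation). Among them were the contractile and calcium-binding protein genes mylpfa (log2 -3.24), pvalb2 (-3.64), tnnc2 (-3.42) and actc1b (-2.69) and the muscle regulator myod1 (-2.17). The list summed to 489 and 260.3 TPM in the mutant and to 2465, 1979.5 and 4992 in all-arch cells. The Hox, Notch and retinoic acid lists lay above other genes and the blood, dissociation stress and endothelium lists below them, with adjusted p from 5.48e-05 to 0.0178, adjusted p from 0.25 to 0.854 with an estimated correlation, and at most 1 member of each passing adjusted over the list alone. With the block 4 Hox genes and 2 retinoic acid genes passed in that way, and the pigment, epithelium and cell cycle lists passed camera (adjusted p from 0.0078 to 0.018, and from 0.541 to 0.612 with an estimated correlation). The other 15 lists passed in neither fit, with adjusted p from 0.199 to 0.956 without the block. Limma called 0 genes higher and 1 lower of 13206, with 368 at an unadjusted p under 0.05. The call of dlx4b was lost without all-arch replicate 3 (adjusted p = 0.0871) and without edn1 mutant replicate 2 (adjusted p = 0.161), and its adjusted p ran from 4.94e-04 to 0.625 over all alternatives. Without edn1 mutant replicate 1, 3 genes were higher. Adding the jag1b wild-type library to the controls gave 3 lower genes, and rescaling 3 (median of ratios) or 2 (quantiles). With the block and median-of-ratios rescaling together 0 genes were lower, so the call of dlx4b was lost there too.

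**Figure D3:**
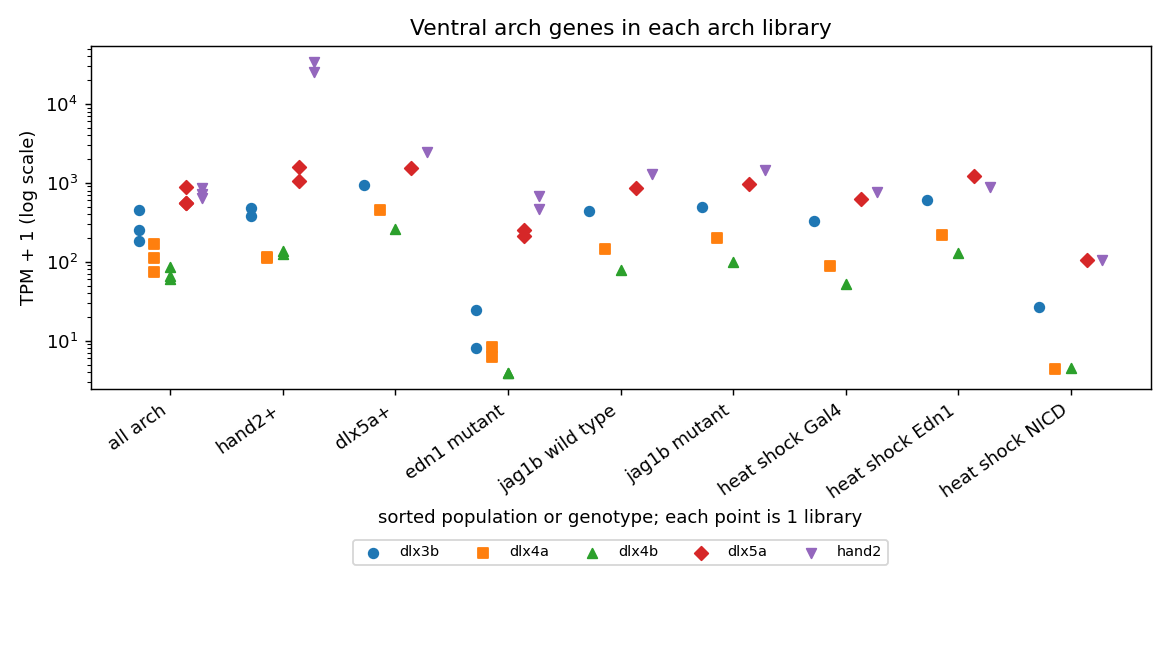
TPM + 1 of dlx3b, dlx4a, dlx4b, dlx5a and hand2 in each arch library, on a log axis. Each point is 1 library. Both edn1 mutant libraries and the heat-shock NICD library lie below the other arch libraries for dlx3b, dlx4a and dlx4b.

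The remaining comparisons rest on 1 library per group, so they have no replicate check and no p-value. A change counted where log2 reached 1 in size with at least 10 TPM in the higher library. By that measure 409 to 1437 genes differed between replicate libraries of the same group, more than the 51 for jag1b and the 221 for Edn1, and 430 differed with NICD. Replicate pairs with a library numbered 1 gave 1171 to 1437, and the only pair without one, all-arch replicates 2 and 3, gave 409. This background thus includes the offset of libraries numbered 1 and may be too wide for the single pairs. Percentiles are those of a list's median among 10000 random lists of like expression. The random lists draw genes independently and so leave out any tendency of a list's genes to vary together. Lists whose genes vary together reach extreme percentiles more easily, so the percentiles describe these libraries and are no test.

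In the jag1b mutant library 11 genes were higher and 40 lower than in its wild type. The lesion gene jag1b stood at -2.25 on the log2 scale. The Notch pathway list, whose ligand Jag1b is, had a median of -0.34 (percentile 0, random lists -0.12 to 0.07) with 7 of 21 members 2-fold lower, jag1b included, and 0 higher. Other lists fell as well: blood (median -0.64, 4 of 15 members 2-fold lower), endothelium (-0.38), early crest and glia (-0.41), dissociation stress (-0.27) and Hox (-0.20), each at percentile 0.11 or less, so the fall was not particular to Notch genes. Among the Notch target genes her4.2 stood at 79.6 TPM against 407, her4.1 at 54.2 against 214 and her4.4, outside the list, at 10.5 against 52.4. These are close copies whose reads may be split between them, and against the 3 all-arch libraries the log2 values of her4.2, her4.1 and her4.4 turned to 0.068, 0.16 and 0.64. All-arch cells held less of them than the jag1b wild type, at 117 ± 88.7, 57.5 ± 33.9 and 8.72 ± 6.49 TPM in the same order. The turn thus goes with lower levels in a control that was not matched to the mutant. The dorsal list had a median of -0.39 (percentile 0, random lists -0.16 to 0.08), with 3 of 12 members 2-fold lower: jag1b itself, fgf20b (0.727 against 19 TPM) and nr2f1b (76.5 against 218). Its members pou3f3b (222 against 437), pou3f3a (108 against 192), hey1 (log2 -0.40), nr2f5 (0.09) and six1a (0.04) moved less than 2-fold. The ventral list had a median of 0.17 (percentile 100, random lists -0.16 to 0.08), with dlx3b at log2 0.17, dlx5a at 0.15 and hand2 at 0.17. The intermediate genes emx2 (-0.84) and grem2b (-0.74) were lower and nkx3.2 (0.60) higher, with a list median at percentile 0.0300. Among the largest decreases, beside fgf20b, were keratin genes of the skin, krt91 (0.401 against 33.9 TPM), krtt1c19e (0.62 against 33.5), krt4 (35.3 against 409) and cyt1l (log2 -3.15), and the epithelium list had 8 of 18 members 2-fold lower (percentile 0). In all-arch cells krt4 stood at 379.8 ± 502 TPM (SD, n = 3). The crest gene tfap2a stood at log2 -1.23. The muscle gene myhz1.3, 1 of the 11 higher genes, stood at 41.6 TPM against 14.1 and at log2 -1.47 against the all-arch libraries. On the deposited scale 0 genes were higher and 10 lower.

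With heat-shock Edn1, 144 genes were higher and 77 lower than with Gal4 alone. The median gene lay at 0.19, and the split turned to 69 and 117 with median-of-ratios rescaling and to 84 and 106 with quantiles. The ventral list had a median of 0.48 (percentile 100, random lists -0.02 to 0.35) with 2 of 12 members 2-fold higher. These were dlx4a (218 against 87.2 TPM) and dlx4b (129 against 51.6), and dlx5a (log2 0.97), dlx3b (0.88), dlx6a (0.79) and hand2 (0.21) moved less. The dorsal list lay at percentile 1.54 (median -0.02, random lists -0.00 to 0.36), with pou3f3a at 25.2 against 78.1 TPM and pou3f3b at log2 -0.82, but hey1, a Notch target in the same list, was at 1254 against 522. In the Notch list nrarpb stood at log2 1.67 and the list median at percentile 74.9. The cartilage list had a median of 0.60 (percentile 100, random lists 0.01 to 0.37), with the matrix gene hapln1a at log2 1.17 and sox5 at 0.71, and the intermediate genes grem2b (1.04) and nkx3.2 (0.77) were higher. Large increases were ctgfb (895 against 115 TPM), the lipid receptor gene s1pr3a (125 against 22.8), cyp1a (log2 2.74), klf9 (2.43) and the sterol enzyme gene cyp51 (2.04). Blood genes were among the largest decreases, with hbae3 at 119 against 1353 TPM, hbbe1.1 at 327 against 2293, hbbe3 at log2 -3.21 and klf17 at -3.41 and 12 of 15 list members 2-fold lower. The blood list summed to 570 TPM with Edn1 and 4737 with Gal4 alone, and to 401, 7268 and 1006 in the all-arch libraries. Blood RNA thus differed more between all-arch replicates than in this pair. The Hox list had 6 of 16 members 2-fold lower (percentile 0, median -0.39), such as hoxb5a (-1.03) and hoxb8a (-1.37, but 0.11 against the all-arch libraries). The frontonasal (-0.55), epithelium (-0.48) and neuronal (-0.30) lists had medians at percentile 0.0400 or less. Dissociation stress genes lay at percentile 100, with klf6a at log2 1.26. Their mean log2 value was 7.98 with Edn1 and 7.5 with Gal4 alone, the lowest of the arch libraries. On the deposited scale 27 genes were higher and 11 lower.

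With heat-shock NICD, which keeps Notch signalling on, 304 genes were higher and 126 lower than with Gal4 alone (median gene 0.15; 219 and 174 with median-of-ratios rescaling, 228 and 174 with quantiles, 65 and 24 on the deposited scale). Of 21 Notch genes 12 were 2-fold higher and 1 lower (median 1.71, percentile 100, random lists -0.05 to 0.31). The target her4.1 stood at 2512 against 184 TPM, her4.2 at log2 3.18, her15.1 at 2.47, hey1 at 1.82 and hey2 at 2.63, and her4.3, outside the list, at 4.07. The feedback genes nrarpa (1.89) and nrarpb (3.39), the receptor gene notch3 (2.15) and the ligand gene jag1b (81.7 against 33.8 TPM) were higher too. Ventral genes were lower: the list had 9 of 12 members 2-fold lower (median -2.06, percentile 0, random lists -0.12 to 0.34), with dlx4a at 3.38 against 87.2 TPM, dlx3b at 25.5 against 329, dlx4b at log2 -3.55, dlx5a at -2.55, and hand2 at 104 against 769 TPM. The joint gene nkx3.2 stood at 6.75 against 74.9 TPM, barx1 at 80.4 against 400.4 and fgfbp2a at log2 -4.69. Dorsal genes were higher, 4 of 12 by 2-fold (median 0.71, percentile 100, random lists -0.11 to 0.33), and the 4 were pou3f3b (1.42), fgf20b (1.22) and, shared with the Notch list, hey1 and jag1b. Genes of early crest and glia were higher as well, 5 of 6 by 2-fold (median 1.65, percentile 100), with fabp7a (2.55), foxd3 (1.77) and sox2 (1.76), beside sox10, used for the sort, at 304 against 64.5 TPM and ednrab at log2 1.73. Neuronal genes (median -0.79, 2 of 9 2-fold lower) and blood genes (-0.70, 7 of 15) were lower, both at percentile 0. The blood list summed to 1697 TPM with NICD, 4737 with Gal4 alone and from 401 to 7268 in the all-arch libraries. Among the largest increases were stc2a (283 against 9.28 TPM), the paired channel subunit genes abcc9 (log2 4.44) and kcnj8 (138 TPM against 7.09), and sox18 (3.92). Dissociation stress genes moved with these changes, 10 of 20 by 2-fold (percentile 100), such as egr2a (1.98), dusp2 (1.47) and fosab (11016 TPM against 5129). Their mean log2 value was 8.42 with NICD and 7.5 with Gal4 alone, the lowest of the arch libraries.

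Genes called in the hand2 comparison were followed across the perturbations with a control of their own. They are not sets of ventral and dorsal genes: of the ventral list only hand2 was called higher, beside heart and posterior Hox genes, phox2bb and krt5, and the ventral list itself had a median of 0.48 with Edn1. The 37 genes higher in hand2 cells had a median log2 of -0.04 in the jag1b mutant (percentile 13.6), -0.22 with Edn1 (percentile 0) and -0.28 with NICD (percentile 0). The 164 genes lower in hand2 cells stood at -0.14 (percentile 0), -0.08 (percentile 0) and 0.02 (percentile 0.01), each beside random lists near the median gene. With the 100 genes of the most negative moderated t, or with quantiles, the Edn1 and NICD medians of the lower genes were lower, and that with NICD was below 0. In edn1 mutants against the jag1b wild-type library the higher genes stood at -0.49 (percentile 0) and the lower genes at 0.50 (percentile 100, random lists 0.18 to 0.33). Against all-arch cells, the controls shared with the hand2 comparison, they stood at 0.27 and -0.23, where simulated unchanged groups gave 1.13 and -0.76. The simulation took the genes with the largest simulated change, which favours noisy genes, and not genes past the threshold. It also let all libraries vary independently. Its values are therefore no expectation for these genes, and no conclusion is drawn from the difference.

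Across 13187 genes, which are not independent replicates, the log2 changes of edn1 mutants and heat-shock Edn1 had a Pearson r of 0.00877 (Spearman's rho -0.0356), those of the jag1b mutant and NICD -0.0457 (rho -0.00465), of edn1 mutants and NICD 0.138 (rho 0.0944) and of the jag1b mutant and Edn1 0.208 (rho 0.243). Heat-shock Edn1 and NICD, which share a control, had an r of 0.303 (rho 0.29) beside a simulated 0.499 (rho 0.458), and a covariance of 0.0734 beside a simulated 0.324. The simulated spread came from the fit of the all-arch, hand2, dlx5a and edn1 mutant libraries. Replicate pairs of that fit differed in 409 to 1437 genes, against 221 and 430 in the heat-shock pairs. The simulated values therefore do not tell how much of the agreement the shared control brings. The hand2 and edn1 mutant comparisons had an r of 0.271 (rho 0.38) beside a simulated 0.398 (rho 0.363), and a covariance of 0.0815 beside a simulated 0.108. That simulation let libraries vary independently. Deviations of same-numbered libraries were correlated at 0.476 (all-arch and hand2), 0.577 (all-arch and edn1 mutant) and 0.621 (hand2 and edn1 mutant). The simulated values leave such pairing out. With 1 called gene in the edn1 comparison, an overlap of calls carries no information. The shared controls, 3 all-arch libraries and 1 Gal4 library, contribute to these values and are too few to split into replicated groups.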

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

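The block with median-of-ratios rescaling and the block for gene lists were chosen after the data were seen. So were the removal of all replicate 1 libraries and the removal of globin genes. Other alternatives were fixed before. The design fixed at the start had named the deposited scale, so the multiplied values used for the main results depart from that design. Counts are given as higher and lower genes, and the cause of each change was not tested unless stated. Over the named genes of tested comparisons, alternatives gave 0 reversals, 3027 values on the same side of the threshold, 301 that no longer passed and 96 that newly passed. Without tests, 646 values moved less than the spread of all-arch replicates, 93 moved more and 5 turned. These 5 were her4.2 (0.068), her4.4 (0.64), her4.1 (0.16) and myhz1.3 (-1.47) in the jag1b mutant and hoxb8a (0.11) with Edn1, each against the 3 all-arch libraries instead of the own control.

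With a pseudocount of 0.1 TPM, 24 genes were higher in hand2 cells and 2 and 68 differed in dlx5a cells. With 5 TPM dlx5a cells gave 30 and 17, hand2 versus dlx5a 9 and 30, the jag1b mutant 5 and 25, Edn1 84 and 51 and NICD 197 higher. With no filter, which changes the number of genes tested, 64 genes were lower in hand2 cells, 192 higher in dlx5a cells, 21 and 163 differed between hand2 and dlx5a cells, 1 was higher in edn1 mutants, 205 were higher than in fli1a-only cells and 2460 lower than in sox10-only cells. With a mean of at least 5 TPM, 25 were higher in hand2 cells, 3 and 3 differed between hand2 and dlx5a cells, 1048 were higher than in fli1a-only cells, and 304 and 675 differed from sox10-only cells.

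Median-of-ratios rescaling shifted the median gene by -0.72 (fli1a-only), 0.40 (dlx5a), -0.27 (hand2 versus dlx5a), -0.21 (Edn1) and -0.17 (NICD). It gave 239 and 994 against fli1a-only cells, 959 higher than sox10-only cells, 36 higher in dlx5a cells, 3 and 9 between hand2 and dlx5a cells, 3 lower in edn1 mutants, and 69 and 117 with Edn1. Quantile normalization gave 802 lower than fli1a-only cells, 1324 higher than sox10-only cells, 346 arch-enriched, 65 higher in hand2 cells, 23 and 23 in dlx5a cells, 3 and 11 between hand2 and dlx5a cells, 2 lower in edn1 mutants, and 84 higher with Edn1. All 19 libraries in 1 fit gave 2316 higher than fli1a-only cells, 23 and 80 in dlx5a cells, 15 and 18 between hand2 and dlx5a cells, and 4 lower in edn1 mutants. Limma without trend or robust estimation changed no count by over 1.5 times.

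The replicate block gave 6353 and 879 against fli1a-only cells, 855 higher than sox10-only cells, 583 arch-enriched, and 94 and 290 in hand2 cells. Beyond the calls given with the results, it changed no other call of a named gene or list. With median-of-ratios rescaling as well, the block gave 1420 and 1964 (fli1a-only), 2323 and 2684 (sox10-only), 847 arch-enriched, 65 higher in hand2 cells and 0 lower in edn1 mutants. The sox10-only library of the arch stage alone gave 207 higher and 91 arch-enriched. The jag1b wild-type library added to the controls gave 3 lower genes in edn1 mutants.

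Leaving out 1 library at a time, genes higher than in fli1a-only cells ranged from 93 to 4320 and lower ones from 279 to 476, genes higher than in sox10-only cells from 344 to 486 and lower ones from 1066 to 1505, and arch-enriched genes from 58 to 324. Genes higher in hand2 cells ranged from 8 to 14 and lower ones from 24 to 54, in dlx5a cells from 0 to 2 and 0 to 6, and in edn1 mutants from 0 to 3 and 0 to 1. Groups left with 1 library were assumed to vary like the others. Without the replicate 1 libraries of all groups, 1016 genes were higher than in fli1a-only cells, with fewer samples in the fit. The hand2, dlx5a and edn1 mutant groups then held 1 library each and the spread of their fit came from all-arch libraries alone, so that fit could not test their calls.

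On the deposited scale the counts were 1537 and 175 (fli1a-only), 223 and 413 (sox10-only), 18 and 66 (hand2), 4 and 4 (dlx5a), 3 and 6 (hand2 versus dlx5a), 0 and 10 (jag1b), 27 and 11 (Edn1) and 65 and 24 (NICD). This scale raises the minimum and the pseudocount to 10.7 TPM of the main scale. With globin genes left out, 175 and 774 genes differed from fli1a-only cells and 112 were arch-enriched. With an estimated correlation 0 lists passed in each of the 6 comparisons. Fry passed 9 lists (fli1a-only), 6 (hand2), 4 (dlx5a), 5 (hand2 versus dlx5a) and 2 (edn1).

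For single libraries, a minimum of 1 TPM gave 91 and 178 (jag1b), 312 and 318 (Edn1) and 663 and 472 (NICD), and one of 50 TPM gave 0 and 15, 54 and 19, and 102 and 43. Against the 3 all-arch libraries 108 and 429 genes differed in the jag1b mutant, 424 were lower with Edn1 and 476 lower with NICD. Genes higher in hand2 cells had a median of -0.0636 with Edn1 when the 100 genes with the largest moderated t were taken, -0.47 with NICD at a pseudocount of 0.1 TPM, and -0.14 (100 genes) or -0.69 (quantiles) in edn1 mutants against the jag1b wild-type library. Genes lower in hand2 cells had a median of -0.15 (100 genes) or -0.26 (quantiles) with Edn1, -0.12 or -0.17 with NICD, and 0.71 or 0.31 in edn1 mutants against that library. The correlation of the jag1b mutant and Edn1 was 0.339 over genes with a mean of at least 10 TPM. What depth limits is unknown for TPM.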

Other observations

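All tests of explanations given here were chosen after the results were seen. The inducible heat shock gene hsp70l stood at 514 TPM in the jag1b mutant and 687 in its wild type, against at most 209 in the all-arch libraries. It stood at 108, 135 and 130.2 in the heat-shocked Edn1, NICD and Gal4 libraries, and at 1675 in fli1a-only replicate 2. The skin keratin gene krt5 stood at log2 -1.83 in the jag1b mutant, cyt1 at -2.48 and the claudin gene cldne at -1.21.

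With heat-shock NICD some genes of other lineages were higher than with Gal4 alone, without replicates. The melanocyte genes pmela (15.5 TPM against 1.5) and tyrp1b (11.2 against 1.71) and the otolith gene stm (log2 2.56) were among them. The vessel list had a median of -0.04 at percentile 9.98, though sox18 was among the largest increases. In the jag1b mutant the Notch ligand gene dlc stood at log2 -1.35 and dlb at -1.13, and with NICD dlc stood at 1.71 and dld at 1.85.

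Heart genes were higher in hand2 cells, and hand2 is itself active in the heart, so heart or other cells with hand2 in the gate may account for part of the difference. If 1 admixed population brought them, their ratio between the hand2 libraries would vary little from gene to gene; its SD on the log2 scale was 1.15 over 8 heart genes, at percentile 88.5 of 10000 random lists with a median SD of 0.7. The value lies between both predictions, so admixed cells and a change within arch cells cannot be told apart, with 2 libraries. Scaling is argued against, since the list median was 2.92 with median-of-ratios rescaling. The levels in the hand2 libraries were 63.1 and 197 TPM for cmlc1, 7.51 and 68.1 for myh6, 11.3 and 32.7 for myl7, 2.78 and 28.9 for nppa and 5.74 and 4.99 for vmhc. The titles of the hand2 libraries name sox10 beside hand2, so the sort would leave out heart cells without the sox10 reporter, and do not name fli1a. The sox10-only libraries, sorted without fli1a signal, held summed heart TPM of 93.7, 261 and 79.9, beside 101 and 369 in hand2 cells and 1.62 in the dlx5a library, whose title does not name fli1a either. A sort without fli1a therefore stays open as a source, and was not tested. For the posterior Hox genes and phox2bb, other cells in the hand2 gate stay open in the same way and were not tested.

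Skeletal muscle genes were lower in edn1 mutants. Scaling is argued against, with a list median of -2.72 under median-of-ratios rescaling. Muscle RNA from other cells that varies between sorts may account for it: all 5 arch libraries of the jag1b and heat-shock sets, which lack the edn1 lesion, also lay below the lowest all-arch library in summed muscle TPM. They held from 122 to 914 TPM. The hand2 (1887 and 5847 TPM), dlx5a (1820 TPM) and single-positive libraries (2599 to 8924 TPM) held more. Low muscle RNA thus went with whole sets of libraries, so a difference between sets and the edn1 lesion cannot be told apart here. An effect of the edn1 lesion on muscle carried into the sort stays open and was not tested. The gate asked for both reporters.

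The median gene lay 0.68 higher in all-arch than in fli1a-only cells. Globin transcripts taking a share of the fli1a-only TPM may account for most of it, since the median was 0.0785 with globin genes left out. The library with the highest globin share is argued against as the sole source, with 0.45 left without it. A biological difference in RNA content stays open and was not tested.

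The 6 libraries of each gate comparison allow 10 splits, too few for a share under 0.05. In the fli1a-only comparison 1 of 10 splits, the real one with 1006 genes, gave as many, and the highest other gave 2. In the sox10-only comparison 1 of 10 gave as many, with 1915 genes against a highest other of 0. For arch-enriched genes 2 of 100 drawn splits of the 9 libraries gave as many as the real 187, with a highest other of 894. These splits do not keep the replicate numbers, which were taken to pair the libraries. Of 100 splits drawn from the 108 that keep 1 library of each number in each group, 6 gave as many, the real one included, with a highest other of 1221. By that count chance among splits that keep the replicate numbers cannot be excluded, but the other 5 all took a whole population as arch cells, the sox10-only libraries in 4 and the fli1a-only libraries in 1, which points to the structure of the samples. The 88 splits whose arch group mixed populations each gave 0 genes.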
